A study of Morchella sextelata with 15 samples.

How the data were processed

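RNA was sequenced from mycelium of the cultivated black morel Morchella sextelata, an ascomycete fungus, in 15 libraries. Per the labels, 3 libraries came from each of 5 groups, namely trifluralin, pendimethalin, S-metolachlor, acetochlor and a control on medium without herbicide. Per the series description, the cultures grew on potato dextrose agar at 20 °C for 5 days, and each herbicide was added at 10 times its normal application concentration. The 4 doses are therefore the same multiple of each product's own rate and not the same concentration. Growth measurements were not analysed here.

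The authors deposited 2 tables of the same 20602 transcripts. The first table holds expected counts, estimated fragments per transcript that are mostly not whole numbers and are not scaled to a common total. The second deposited table holds FPKM, the fragment number scaled by transcript length and library total. For each transcript, the expected count divided by the FPKM was the same in all libraries up to a factor per library, with the lowest counts left out. The largest relative deviation was 8.4e-07. Transcript lengths are not given, so this ratio was taken as the relative length. Low expected counts lay on steps that depended on the transcript, so that 1 fragment can count as more than 1. Per the submitters' processing notes, Trimmomatic, Bowtie2 and DESeq were used, with no versions, and the build named is mm10, a mouse build. All 20602 row names have the form of a de novo Trinity assembly and none belongs to that build. The assembler's settings and the counting program are not given in the sources used here.

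Without their isoform number and last digit, the row names fall into 14056 Trinity genes, of which 5051 have more than 1 row. Each name ends in a digit of 5 kinds whose meaning is not given in the sources used here. If it marks the group whose reads gave the assembled transcript, the listing favours transcripts abundant in that group, and the numbers called higher and lower per herbicide are open to that. Names of 1 Trinity gene may in that case come from separate assemblies and need not belong to 1 gene. The sums per Trinity gene described below may then add up transcripts of different genes. None of the names matched the 13182 genes of the reference gene table. The files do not pair the transcripts with gene names, so the planned tests of gene lists, such as tubulins and fatty acid elongases, and the planned rule for genes with informative product names could not be run. The rule's fallback was used, under which the text names, per comparison, the 2 transcripts with the largest rise and the 2 with the largest fall among those with an adjusted p under 0.05, no overlap between the groups' libraries and a mean of at least 10 CPM in the higher group. Reads shared between near-identical transcripts, isoforms or overlapping transcripts on both strands may have been divided by the authors' counting, so a single transcript's value is uncertain in that respect.

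Expected counts were rounded to whole numbers, although the design written beforehand assumed raw counts. Transcripts were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which kept 17555 and removed 3047. Libraries were scaled by TMM. All 15 libraries entered 1 quasi-likelihood fit with 1 mean per group, and 7 contrasts were tested, each herbicide against control, pendimethalin against trifluralin, acetochlor against S-metolachlor, and the mean of the 2 dinitroanilines against the mean of the 2 chloroacetanilides. P-values were adjusted by the Benjamini-Hochberg method, and a transcript was called at an adjusted p under 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. The groups differed in spread, with a biological coefficient of variation of 0.42 in control, 0.43 in trifluralin, 0.55 in pendimethalin, 0.29 in S-metolachlor and 0.40 in acetochlor, whereas the fit shares its estimate of the spread among them. CPM values given are TMM-scaled. Where a group had 0 counts, a fold was computed against a floor of 3 fragments over the group, each worth the largest count on the lowest step of that transcript and at least 1. Where a group had 1 to 3 fragments, with 1 fragment taken as the middle of that step, the ratio is given with its counting interval. Intervals and floors cover counting error only.

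Library totals ranged from 22923346 to 24766457 expected counts. On simulated counts for the same 17555 transcripts with 200 changed, the test recovered 67% of 4-fold and 9% of 2-fold changes for trifluralin against control, 73% and 10% for pendimethalin, 65% and 6% for S-metolachlor, and 56% and 7% for acetochlor. It recovered 73% and 11% for pendimethalin against trifluralin, and 66% and 11% for acetochlor against S-metolachlor. The 200 changed transcripts are fewer than each comparison with control called, which makes the Benjamini-Hochberg cut-off stricter in the simulation. These shares are therefore not the power of those comparisons. Pairs of libraries of a group differed by 28.9 to 365.8 in chi-square per degree of freedom, so none was counted as a duplicate. The labels do not say that the libraries of a group came from separate cultures, and p-values then measure the spread between these samples, which may be technical.

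Overlaps between comparisons that share the control libraries were set beside 20 simulations of unchanged groups against those controls and beside the overlap of independent lists. The 3 controls could not be split so that each part keeps 2. The alternatives planned before the data were examined were DESeq2 1.42.0, RLE scaling, no filter or a stricter one (5 CPM in 3 libraries), a fit with only the compared groups, the replicate number as a block, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), and each library left out in turn with the full set of tested transcripts. Counts summed per Trinity gene, and a run without a set of transcripts that stood out in 1 library, were added after the data were seen. Other computations used R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.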

Results

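The transcriptome of Morchella sextelata mycelium was measured on herbicide-free medium and on medium with 1 of 4 herbicides. Trifluralin and pendimethalin are dinitroanilines, which block microtubule assembly in plants. S-metolachlor and acetochlor are chloroacetanilides, which block the synthesis of very-long-chain fatty acids in plants. Each group had 3 libraries, whose totals of expected counts ranged from 23921235 to 24309184 in control, 24237135 to 24728350 with trifluralin, 24071293 to 24766457 with pendimethalin, 23571506 to 24053546 with S-metolachlor and 22923346 to 24592427 with acetochlor. Of the 20602 transcripts, 17945 ± 141 (SD, n = 3) had counts in the control libraries and 19281 ± 403 in the S-metolachlor libraries, or 17754 ± 111 and 18238 ± 101 without a set of 1373 transcripts that stood out in S-metolachlor replicate 1.

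The S-metolachlor libraries lay apart from all others. Their Spearman correlation across transcripts with control libraries had a median of 0.821 (0.781 to 0.856 over 9 pairs), against 0.966 to 0.978 among themselves and a median of 0.964 among the controls. The median correlation with control was 0.926 for trifluralin, 0.926 for pendimethalin and 0.935 for acetochlor. Transcripts are not independent replicates, so these values only describe the libraries. By mean correlation, each pendimethalin library lay nearer to another group than to its own. Replicates 1 and 2 had means of 0.939 and 0.941 with their own group and 0.957 and 0.947 with trifluralin. Replicate 3 was at 0.925 with its own group, 0.948 with acetochlor, 0.939 with control and 0.936 with trifluralin. The own-group means of replicates 1 and 2 include replicate 3. With each other these 2 correlated at 0.954, against 0.924 and 0.927 for the pairs with replicate 3.

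**Figure D1:**
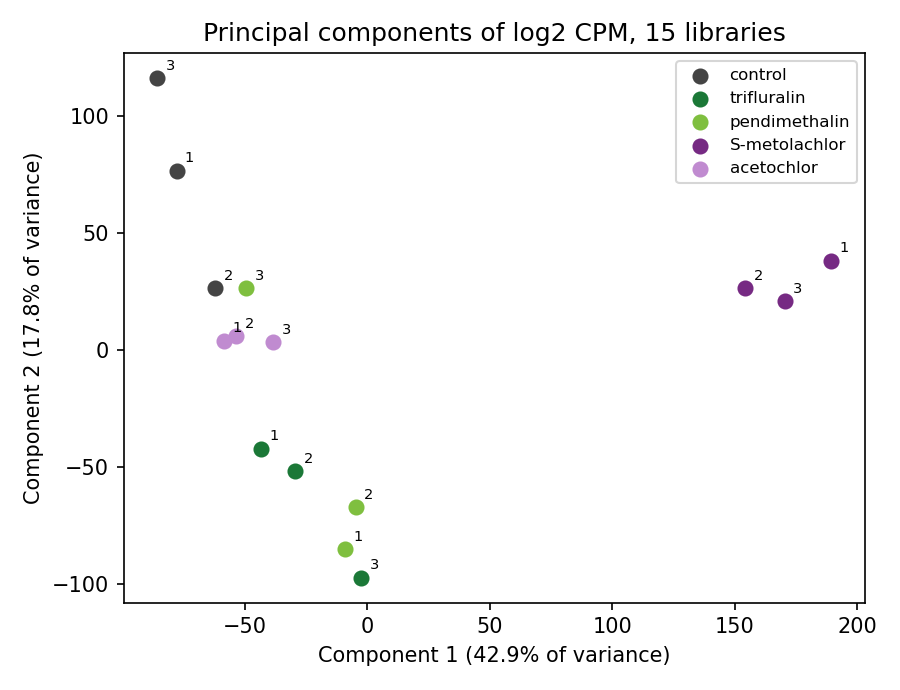
Principal components of log2 CPM for the 15 libraries, with each point 1 library, its colour the group and its digit the replicate number. The first component (42.9% of the variance) separates the 3 S-metolachlor libraries from the other 12, and the second (17.8%) runs from the controls to the dinitroaniline libraries, with pendimethalin replicate 3 beside control replicate 2.

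Trifluralin was compared with control to find the transcripts that changed with a trifluoromethyl dinitroaniline. The largest rise was in TRINITY_DN6716_c0_g1_i9_2, from 0.233 ± 0.282 CPM in control to 218 ± 53.0 CPM with trifluralin (SD, n = 3 each), a log2 fold change of 9.85 (SE 1.04, edgeR adjusted p = 0.000215; 11.52 without control replicate 1). TRINITY_DN7378_c0_g2_i1_1 rose from 0.210 ± 0.0962 to 191 ± 81.3 CPM, by 9.78 on the log2 scale (SE 1.25, edgeR adjusted p = 0.000669). TRINITY_DN13795_c0_g1_i1_3 fell from 442 ± 394 to 4.27 ± 1.78 CPM, a log2 fold change of -6.69 (SE 0.81, edgeR adjusted p = 0.000478; -5.68 without control replicate 3). TRINITY_DN14322_c0_g1_i1_1, at 4460 ± 2040 CPM in control, was at 81.6 ± 93.2 CPM, a log2 fold change of -5.77 (SE 0.90, edgeR adjusted p = 0.00227; -7.33 without trifluralin replicate 1). In each of these, and in every transcript named for a comparison below, all libraries of one side lay above all of the other, as the rule for naming required. Both risen transcripts were also called higher with acetochlor, at 379 ± 194 and 236 ± 37.7 CPM, and with pendimethalin, at 9.83 ± 9.14 and 7.70 ± 11.1 CPM (log2 fold changes 5.38 and 5.14, edgeR adjusted p = 0.00411 and 0.0114), and were at 0.196 ± 0.181 and 0.209 ± 0.0252 CPM with S-metolachlor.

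Over the 17555 transcripts tested, 2578 were called with trifluralin, 1349 higher and 1229 lower, and 1928 of them changed at least 2-fold. Names ending in 4, the digit with the largest excess of rises and picked after the values were seen, held 306 of the rises and 127 of the falls, and the other names 1043 and 1102. For each herbicide below the digit was picked in the same way, which by itself lowers the excess of rises in the other names. The libraries of both groups did not overlap in 98.4% of the called transcripts and in 36.7% of those tested, against 10% by chance. On log2(FPKM + 0.1) with limma, 65.7% of the calls were higher, against 52.3% here, and the median log2 fold change of all transcripts was 0.17, against -0.01. That run changed the scaling, the added constant, the filter and the test together, so the move has no single source. The count was 1044 without control replicate 1, 947 without control replicate 3, 944 without trifluralin replicate 3, 1041 with only the 2 groups in the fit, and 3984 with DESeq2.

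Pendimethalin, a dinitroaniline with ring methyl groups and a branched alkyl amine, was compared with the same controls. TRINITY_DN1147_c0_g1_i1_4 rose from 3.14 ± 1.29 CPM in control to 1690 ± 557 CPM (SD, n = 3 each), a log2 fold change of 9.07 (SE 0.66, edgeR adjusted p = 6.87e-05). It was also called higher with acetochlor (8.50, edgeR adjusted p = 2.97e-05), trifluralin (6.53, 0.000111) and S-metolachlor (1.27, 0.0473). The fitted rise of TRINITY_DN10594_c0_g1_i1_3 was 9.16 (SE 1.97, edgeR adjusted p = 0.0111), but its pendimethalin libraries held 166, 360 and 0.534 CPM against at most 0.419 in control, and its adjusted p was 0.0532 without control replicate 1, 0.0552 without control replicate 3, 0.0544 in limma on log2(FPKM + 1) and 0.0900 with only the 2 groups in the fit (2.33e-08 to 0.0900 over all alternatives); the rise was 8.09 without pendimethalin replicate 2. TRINITY_DN10594_c0_g1_i1_3 was also called higher with trifluralin (8.75, edgeR adjusted p = 0.0124) and S-metolachlor (7.52, 0.00577), but not with acetochlor (2.07, 0.508). TRINITY_DN7848_c0_g1_i4_5 fell from 18.5 ± 4.27 to 0.201 ± 0.111 CPM, a log2 fold change of -6.50 (SE 1.42, edgeR adjusted p = 0.0117). TRINITY_DN5819_c0_g1_i2_4 fell from 106 ± 61.9 to 2.29 ± 1.95 CPM, a log2 fold change of -5.53 (SE 0.87, edgeR adjusted p = 0.00271; -6.40 without pendimethalin replicate 1), and was also called lower with each of the other herbicides.

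With pendimethalin 2263 transcripts were called, 1290 higher and 973 lower, of which 1741 changed at least 2-fold. Names ending in 4 held 403 of the rises and 80 of the falls, and the other names 887 and 893. The groups' libraries did not overlap in 28.2% of the tested transcripts, against 10% by chance. On log2(FPKM + 0.1) 69.0% of limma's calls were higher, against 57.0% here, with a median log2 fold change of 0.19 against 0.02. The count was 304 (101 higher, 203 lower) with only the 2 groups in the fit, 852 without control replicate 1, 942 without control replicate 3, 1349 without pendimethalin replicate 1, 1174 without pendimethalin replicate 2, and 3533 with DESeq2; without pendimethalin replicate 3 it was 3152.

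S-metolachlor changed the most transcripts of the 4 herbicides. TRINITY_DN6798_c1_g1_i1_4 had 0 counts in the control libraries and 52.8 ± 7.13 CPM with S-metolachlor (SD, n = 3), at least 295-fold higher (edgeR adjusted p = 4.64e-05). TRINITY_DN5638_c0_g1_i1_5, also at 0 in control, reached 29.7 ± 4.79 CPM, at least 602-fold higher (edgeR adjusted p = 9.45e-06). TRINITY_DN10966_c0_g1_i1_3 had 34.9 ± 23.1 CPM in control and 0 counts with S-metolachlor, at least 255-fold lower (edgeR adjusted p = 0.00571; at least 162-fold without control replicate 3). TRINITY_DN2242_c0_g1_i1_1 fell from 1000 ± 330 to 0.395 ± 0.317 CPM, a log2 fold change of -11.30 (SE 1.41, edgeR adjusted p = 6.04e-05; -12.03 without S-metolachlor replicate 1), and was called lower with the other 3 herbicides too, at 80.7 ± 101, 54.8 ± 47.9 and 8.69 ± 6.90 CPM with trifluralin, pendimethalin and acetochlor.

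With S-metolachlor 8098 transcripts were called, 46.1% of those tested, 4283 higher and 3815 lower, and 6313 changed at least 2-fold. Names ending in 1 held 1499 of the rises and 786 of the falls, and the other names 2784 and 3029. With the set that stood out in replicate 1 left out, falls outnumbered rises in names ending in 2 (663 and 333) and 4 (774 and 575). Rises outnumbered falls in names ending in 3 (985 and 803) and 5 (887 and 789). The libraries did not overlap in 62.9% of the tested transcripts, against 10% by chance. Limma on log2(FPKM + 1) placed 64.6% of its calls higher, against 52.9% here, with a median log2 fold change of 0.23 against 0.09. Of the 1373 transcripts that stood out in S-metolachlor replicate 1, 164 were tested and 162 of them called. When that set was left out, an alternative added after the data were seen, 7934 were called.

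Acetochlor was compared with the same controls. TRINITY_DN7704_c0_g1_i7_5 had 0 counts in control and 17.4 ± 4.83 CPM with acetochlor (SD, n = 3), at least 274-fold higher (edgeR adjusted p = 8.08e-05). TRINITY_DN8108_c0_g1_i7_1 rose from 0.0616 ± 0.0274 CPM, 3 fragments in all, to 187 ± 36.2 CPM, a ratio of 2690 with a 95% counting interval of 922 to 13100 (edgeR adjusted p = 0.000415). TRINITY_DN8733_c0_g2_i1_1 fell from 65.2 ± 56.0 to 0.133 ± 0.0519 CPM, a log2 fold change of -8.91 (SE 1.87, edgeR adjusted p = 0.0117; -9.53 without control replicate 3), and TRINITY_DN7919_c0_g1_i3_3 from 62.7 ± 55.1 to 0.130 ± 0.0131 CPM, 3 fragments in all, a ratio of 551 with a 95% counting interval of 188 to 2670 (edgeR adjusted p = 0.0106). In both, control replicate 3 was far below the other controls, at 1.65 and 1.2 CPM. Both risen transcripts were also called higher with trifluralin, at 3.53 ± 0.797 and 44.0 ± 24.2 CPM.

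With acetochlor 1706 transcripts were called, 923 higher and 783 lower, and 1209 changed at least 2-fold. Names ending in 2 held 197 of the rises and 57 of the falls, and the other names 726 and 726. The libraries did not overlap in 28.9% of the tested transcripts, against 10% by chance. On log2(FPKM + 0.1) 62.3% of limma's calls were higher, against 54.1% here, whereas with only the 2 groups in the edgeR fit 357 were higher and 427 lower. The count was 638 without control replicate 1, 931 without control replicate 3, 984 without acetochlor replicate 1, 784 with only the 2 groups in the fit, and 2838 with DESeq2. It was the lowest of the 4 herbicides with all libraries in the fit, but not with only the compared groups in it, where pendimethalin called 304.

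**Figure D2:**
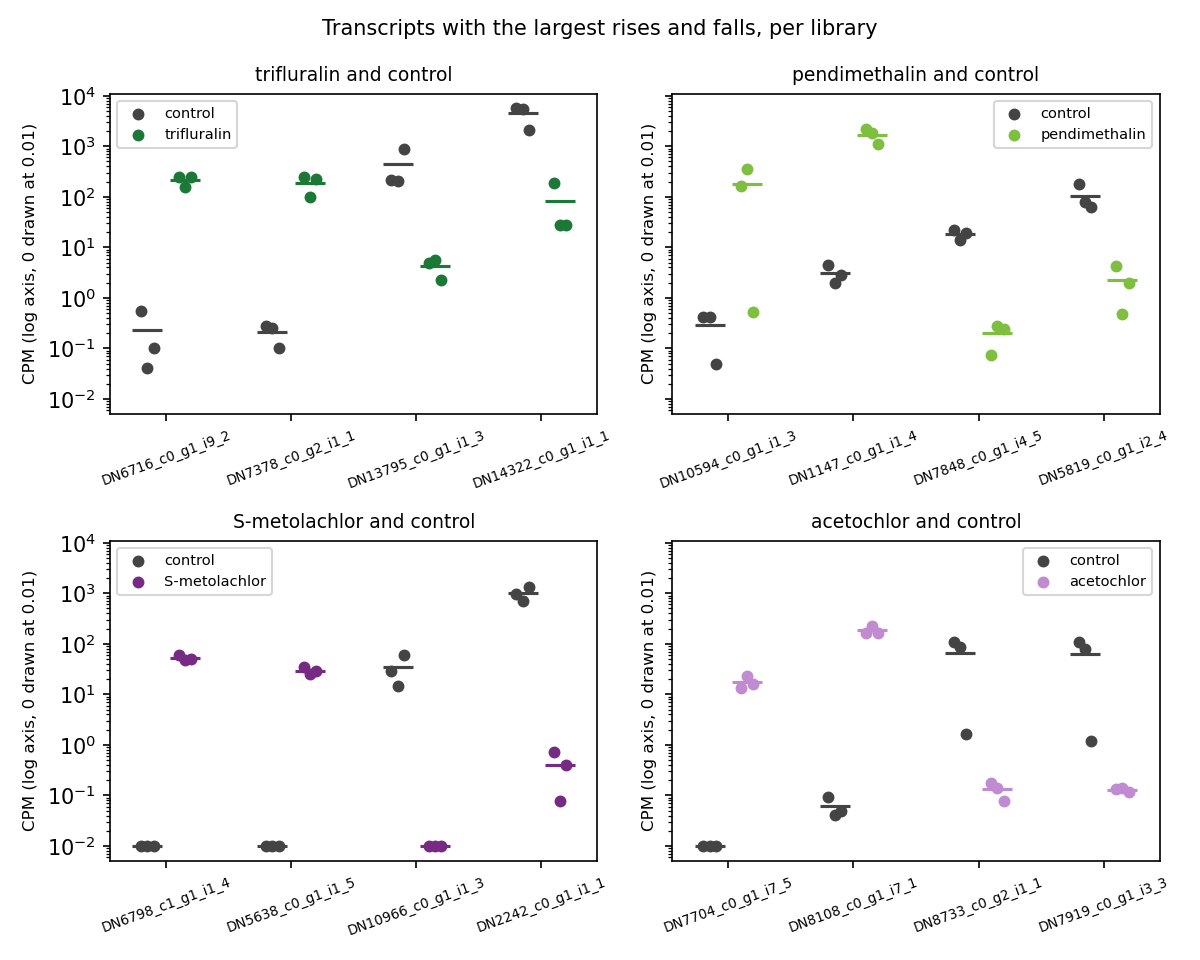
CPM of the named transcripts in each herbicide group and in control, on a log axis with 0 drawn at 0.01; points are libraries and lines are group means (n = 3). TRINITY_DN6798_c1_g1_i1_4, TRINITY_DN5638_c0_g1_i1_5 and TRINITY_DN7704_c0_g1_i7_5 have 0 counts in all 3 control libraries, and 1 pendimethalin library of TRINITY_DN10594_c0_g1_i1_3 lies at 0.534 CPM near the controls.

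The 2 dinitroanilines were compared with each other at the same multiple of their rates. TRINITY_DN1863_c0_g1_i1_2 was at 2050 ± 947 CPM with pendimethalin and 156 ± 91.3 CPM with trifluralin (SD, n = 3 each), a log2 fold change of 3.72 (SE 0.52, edgeR adjusted p = 0.00598). TRINITY_DN6633_c0_g1_i4_4 was at 21.7 ± 9.68 against 0.959 ± 0.320 CPM, a log2 fold change of 4.49 (SE 0.85, edgeR adjusted p = 0.0403), and lost its call without any 1 of the 6 libraries, with adjusted p from 0.0511 without pendimethalin replicate 1 to 0.207 without trifluralin replicate 3, and with the replicate block (adjusted p = 0.1; 1.58e-06 to 0.207 over all alternatives). TRINITY_DN923_c0_g1_i1_3 was at 0.557 ± 0.123 CPM with pendimethalin and 221 ± 266 CPM with trifluralin, a log2 fold change of -8.62 (SE 0.96, edgeR adjusted p = 0.00188). TRINITY_DN5239_c0_g1_i1_1 was at 3.68 ± 2.38 against 661 ± 768 CPM, a log2 fold change of -7.49 (SE 0.97, edgeR adjusted p = 0.00363). In both of the latter, trifluralin replicate 1 was the highest, at 527 and 1550 CPM, and without it the log2 fold changes were -6.91 and -5.89; that of TRINITY_DN5239_c0_g1_i1_1 was -8.08 without pendimethalin replicate 3.

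Between these herbicides 72 transcripts were called, 12 higher and 60 lower with pendimethalin, and the libraries did not overlap in 10.0% of the tested transcripts, which is the share chance gives. The median 95% interval of a log2 difference reached 0.94 to either side. The interval lay within 2-fold in both directions for 6715 transcripts, 38.4% of those for which one could be computed. For the other transcripts a 2-fold difference was not excluded. With only these 2 groups in the edgeR fit 0 transcripts were called, the 4 named ones included, and 825 had an unadjusted p under 0.05 where chance gives 878, whereas DESeq2 with all groups called 215. The count was 45 without trifluralin replicate 1, 34 without trifluralin replicate 3, 38 without pendimethalin replicate 1 and 29 without pendimethalin replicate 2.

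S-metolachlor and acetochlor share a chloroacetyl group on a substituted aniline and differ in the alkoxyalkyl group on the nitrogen. TRINITY_DN7458_c0_g1_i3_3 was at 246 ± 67.4 CPM with acetochlor and had 1 fragment in the S-metolachlor libraries (SD, n = 3), a ratio of 14700 with a 95% counting interval of 2640 to 581000 (edgeR adjusted p = 6.90e-06; a ratio of 9700 without S-metolachlor replicate 2, and at least 3330-fold higher without replicate 3, which held that fragment). TRINITY_DN7825_c0_g1_i2_5 was at 1190 ± 103 CPM with acetochlor and 0.169 ± 0.147 CPM with S-metolachlor, taken as 2 fragments in all, a ratio of 6840 with a 95% counting interval of 1890 to 56500 (edgeR adjusted p = 1.04e-05), with 37.6 ± 6.44 CPM in control. TRINITY_DN8729_c0_g2_i1_1 and TRINITY_DN12301_c0_g1_i1_1 had 0 counts with acetochlor and were at least 623-fold and 103-fold lower than with S-metolachlor (edgeR adjusted p = 0.00147 and 0.00214). Their S-metolachlor means rest on replicate 1, with 70.0 CPM against 3.27 and 7.42 CPM in the first and 67.9 CPM against 1.38 and 4.29 CPM in the second, and without it they were at least 124-fold and 12-fold lower.

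Between the chloroacetanilides 6555 transcripts were called, 3137 higher and 3418 lower with acetochlor, and 5047 of them differed at least 2-fold. The libraries did not overlap in 57.0% of the tested transcripts, against 10% by chance. Limma on log2(FPKM + 1) placed 37.2% of its calls higher with acetochlor, against 47.9% here, with a median log2 difference of -0.12 against -0.03.

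The mean of the dinitroanilines was set against the mean of the chloroacetanilides to compare the 2 classes, as a difference between averages of the herbicides' log2 means, which is not the log2 ratio of the class means in CPM. TRINITY_DN3895_c0_g1_i2_4 was at 2960 ± 1730 CPM over the dinitroaniline libraries and 77.2 ± 135 CPM over the chloroacetanilide libraries (SD, n = 6 each), a log2 difference of 7.0 (SE 0.62, edgeR adjusted p = 2.28e-05; 7.77 without acetochlor replicate 2; a 38.3-fold ratio of the class means), with 441 ± 270 CPM in control. In that transcript S-metolachlor was at 2.94 ± 0.483 CPM and acetochlor at 152 ± 171 CPM, the latter not called against control (edgeR adjusted p = 0.181). TRINITY_DN2242_c0_g1_i1_1 was at 67.8 ± 72.3 against 4.54 ± 6.30 CPM. Its log2 difference was 5.16 (SE 0.78, edgeR adjusted p = 0.000655), or 4.23 without trifluralin replicate 2, with a 14.9-fold ratio. Control was at 1000 ± 330 CPM, and each herbicide was called lower. SDs over 6 libraries include the difference between a class's herbicides. TRINITY_DN5579_c0_g2_i1_1 was at 1.67 ± 1.81 against 31.9 ± 32.3 CPM, a log2 difference of -5.19 (SE 0.80, edgeR adjusted p = 0.000755; -6.91 without pendimethalin replicate 3; 19.1-fold), most of it from S-metolachlor at 59.6 ± 17.6 CPM and less from acetochlor at 4.28 ± 0.331 CPM. TRINITY_DN5538_c0_g1_i1_5 was at 5.27 ± 1.46 against 112 ± 65.9 CPM, a log2 difference of -4.42 (SE 0.48, edgeR adjusted p = 7.89e-05; -3.75 without acetochlor replicate 3; 21.3-fold).

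The class contrast called 4191 transcripts, 2209 higher and 1982 lower with the dinitroanilines, whereas limma on log2(FPKM + 1) called 2109 higher and 2648 lower (44.3% higher against 52.7% here). In 603 of the calls acetochlor and S-metolachlor lay on opposite sides of the dinitroaniline mean. All 6 libraries of one class lay above all 6 of the other in 650 tested transcripts (3.7%), and 614 of these were called, 356 higher and 258 lower with the dinitroanilines. Exchangeable libraries give 0.22%, but libraries of 1 herbicide are not exchangeable, and the 2 other ways of pairing the herbicides parted 266 transcripts (trifluralin with acetochlor) and 153 (trifluralin with S-metolachlor), so that 3 pairings are too few to test a class effect.

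**Figure D3:**
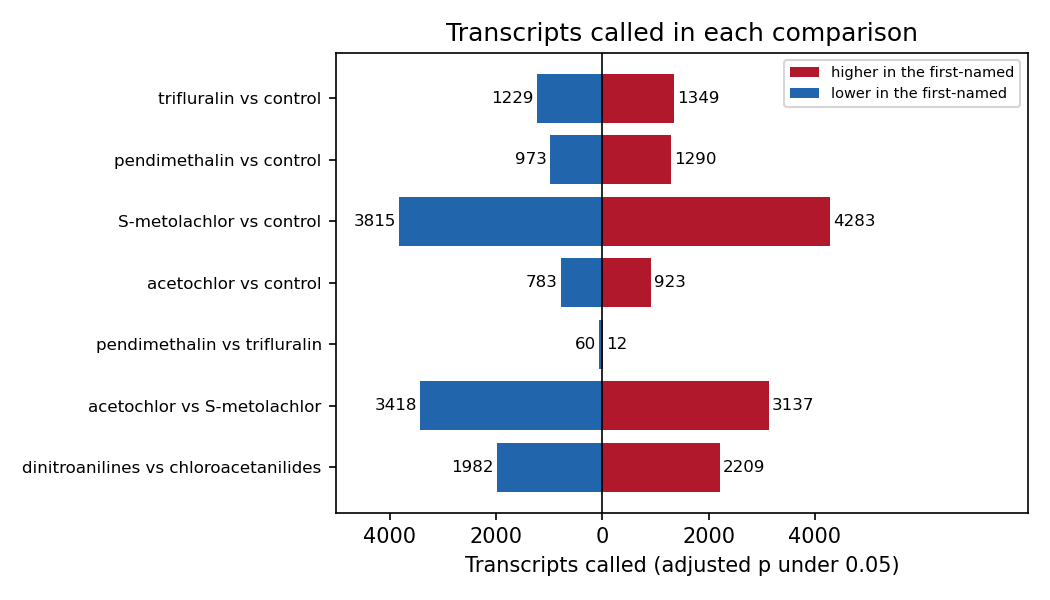
Transcripts called in each of the 7 comparisons at an edgeR adjusted p under 0.05, with red bars to the right for those higher and blue bars to the left for those lower in the first-named side. S-metolachlor against control has 4283 higher and 3815 lower, and pendimethalin against trifluralin has 12 and 60.

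The responses to the 4 herbicides overlapped. Trifluralin and pendimethalin shared 873 transcripts called higher and 698 called lower, with 2 called in opposite directions, where independent lists of these lengths give 99.1, 68.1 and 165.1. S-metolachlor and acetochlor shared 559 and 567, with 101 opposite, against 225.2, 170.2 and 391.6 for independent lists. At least 2-fold changes in both left 695 of the 1126 transcripts that S-metolachlor and acetochlor called the same way. Trifluralin shared 844 and 853 with S-metolachlor (124 opposite) and 549 and 426 with acetochlor (1 opposite). Pendimethalin shared 850 and 734 with S-metolachlor (88 opposite) and 478 and 412 with acetochlor (4 opposite). Unchanged groups simulated against the same controls shared 0 calls in 20 simulations of each pair, which does not show how far shared controls raise the overlap of lists that hold many calls.

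Across transcripts, the correlation of log2 fold changes was 0.78 for the dinitroanilines and 0.38 for the chloroacetanilides, and across the classes 0.64 for trifluralin with acetochlor, 0.58 for pendimethalin with acetochlor, 0.51 for pendimethalin with S-metolachlor and 0.45 for trifluralin with S-metolachlor, against a mean of 0.51 in simulated unchanged groups, which comes from the shared controls. The covariance was 1.51 for the dinitroanilines and 1.15 for the chloroacetanilides, against 0.28 simulated, a difference of 1.23 and 0.87. Across the classes that difference was 1.34 for pendimethalin with S-metolachlor, 1.24 for trifluralin with S-metolachlor, 0.90 for trifluralin with acetochlor and 0.73 for pendimethalin with acetochlor. The dinitroanilines had the highest correlation of the 6 pairs but not the highest covariance, which grows with the size of the response. Part of the shared calls may come from the shared controls, which were too few to split. Among the tested transcripts, 278 were called higher and 289 lower with all 4 herbicides (363 in all at 2-fold or more), and 8265 were called with none. With S-metolachlor 2941 were called higher and 2496 lower that were not called with another herbicide, and 3779 of these were also called between acetochlor and S-metolachlor.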

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

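The 7 comparisons and the counts of splits of their libraries were planned before the data were examined, and the tests that weigh the number of S-metolachlor calls, like the splits that keep each herbicide whole, were chosen after the result was seen.

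The 2 chloroacetanilides moved 101 transcripts in opposite directions against control, 46 higher with S-metolachlor and lower with acetochlor and 55 the reverse. Each of the 101 was also called in the test of the difference between the 2 herbicides, which opposite calls in the same fit make near certain. TRINITY_DN7825_c0_g1_i2_5 is one of them, at 37.6 ± 6.44 CPM in control, 1190 ± 103 CPM with acetochlor and 0.169 ± 0.147 CPM with S-metolachlor (SD, n = 3; edgeR adjusted p = 0.00252 and 6.03e-05 against control, 3 of 3 libraries each).

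S-metolachlor called 8098 transcripts in the main fit, more than 3 times as many as any other herbicide against control. Its margin was smaller in DESeq2 (8889, the next 3984) and with the stricter filter (5750, the next 2435). The tables argue against a smaller spread of its libraries as the whole reason, since the SD of its log2 fold changes at a mean of at least 10 CPM, less the error, was 1.73, which is 1.67 times the next largest (1.04 for trifluralin). They argue against depth too, since mean totals had a ratio of 0.99 to control. Of the 1373 transcripts that stood out in replicate 1, only 164 were tested, and 162 of these were called. They are too few to make up the 8098 calls. Without the set 7934 were called, a result that the small number tested made near certain beforehand. The labels name no batch, so none was tested. A response to S-metolachlor at this dose remains, worded as a hypothesis because it was found and tested on the same data.

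With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 2578 with trifluralin and the highest other 0, 2263 and 679 with pendimethalin, 8098 and 0 with S-metolachlor, 1706 and 1 with acetochlor, and 6555 and 0 between the chloroacetanilides, so in each 1 split called as many as the real one, itself. For pendimethalin against trifluralin 2 of the 10 splits called as many, the real one with 72 and one with 76 that set pendimethalin replicate 1 with trifluralin replicates 1 and 3. For the classes, with 1 mean per class, the real split called 2293 and the highest of the other drawn splits 10. Thus 1 of 41 splits called as many, the smallest share these draws allow. The drawn splits ignore that the libraries come in 4 herbicide groups. Breaking up these groups puts differences between herbicides into the spread, so few calls were likely with or without a class effect. The 2 other splits that keep each herbicide whole were run after that result was seen, and called 711 for trifluralin with acetochlor against the rest and 6 for trifluralin with S-metolachlor against the rest, and 3 such splits are too few for a share under 0.05 for a class effect.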

How the results depend on the processing

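The sums per Trinity gene and the run without the transcripts that stood out in S-metolachlor replicate 1 were added after the data were seen; the other alternatives were planned. Of 125 alternative counts, 101 stayed within 1.5 times the value in the report and 24 did not. DESeq2 called 3984 with trifluralin, 3533 with pendimethalin, 2838 with acetochlor and 215 between the dinitroanilines. With only the compared groups in the fit these were 1041, 304, 784 and 0 (edgeR; 825 at an unadjusted p under 0.05). In the same setting S-metolachlor against control called 8617 and the chloroacetanilides 7362, more than the 8098 and 6555 with all groups. The spread is then estimated from the compared groups alone. The groups' own coefficients of variation were 0.29 in S-metolachlor and 0.55 in pendimethalin, against 0.42 in the shared fit. Causes of these moves were not tested. Leaving out 1 library gave 944 to 3306 with trifluralin, 852 to 3152 with pendimethalin, 638 to 1902 with acetochlor and 29 to 82 between the dinitroanilines, and 6520 to 7784 with S-metolachlor, 4765 to 5509 between the chloroacetanilides and 3009 to 4701 between the classes. With the stricter filter 47.1, 49.4, 49.3 and 46.1% of the calls were higher with trifluralin, pendimethalin, S-metolachlor and acetochlor, and without control replicate 1 49.6, 47.9, 48.7 and 47.3%. With only the compared groups in the fit it was 47.1, 33.2, 51.8 and 45.5%, without control replicate 3 49.6% with S-metolachlor and 49.2% with acetochlor, and without trifluralin replicate 2 49.1% with trifluralin, so which of rises and falls are more numerous depends on these choices. At 2-fold or more, the calls shared by all 4 herbicides went from 567 to 363 and those shared by S-metolachlor and acetochlor from 1126 to 695, since fewer calls qualify. Of 440 alternative values of the named transcripts, 425 kept their direction and call, 15 kept the direction and lost the call (8 of them with 1 library left out), and 0 reversed. Settings whose filter removed a transcript are not among these values. That was so for TRINITY_DN8729_c0_g2_i1_1 and TRINITY_DN12301_c0_g1_i1_1 with the stricter filter, and for the former in both limma runs. With the replicate block the counts were 1890, 1735, 7666, 1276, 54, 5909 and 3539 in the order of the comparisons in the report, and only TRINITY_DN6633_c0_g1_i4_4 of the named transcripts lost its call. No clear pairing of the libraries by replicate number was seen, although these values cannot exclude one. Deviations of same-numbered libraries correlated between -0.44 and 0.40 (median -0.025, 5 of 30 pairs over 0.1). Of 15 libraries, 7 correlated best with their own number. Depth limits the transcripts with few counts. The test recovered at most 11% of simulated 2-fold changes, but with 200 transcripts changed, fewer than each comparison with control called. That share is therefore not the power of those comparisons. The planned gene list tests and their alternatives were not run.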

Other observations

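The tests of the 2 patterns weighed in this part and, in the 2 paragraphs that follow, the ranking by abundance and the shuffles were chosen after the result was seen.

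Among the 100 most abundant transcripts, falls outnumbered rises with each herbicide. Of the 100 with the highest mean log2 CPM over the 2 groups compared, trifluralin called 3 higher and 27 lower, pendimethalin 2 and 24, S-metolachlor 20 and 35, and acetochlor 3 and 17. At ranks 501 to 2000 rises outnumbered falls with trifluralin (211 and 131), pendimethalin (151 and 142) and acetochlor (153 and 131) but not with S-metolachlor (338 and 457). A ranking over all groups, looked at first, gave S-metolachlor 15 and 50 among the 100, and it favours transcripts that are low with that herbicide alone. The 100 most abundant transcripts of each library took 28.0% ± 2.89 of its counts in control (SD, n = 3), 20.86% ± 1.0 with trifluralin, 22.81% ± 1.88 with pendimethalin, 25.46% ± 0.75 with S-metolachlor and 26.26% ± 2.42 with acetochlor, differences that were not tested. The 100 of the ranking over all groups took 24.5% ± 1.5 in control, 18.6% ± 1.7, 20.0% ± 2.1 and 18.3% ± 0.8 with trifluralin, pendimethalin and S-metolachlor (exact permutation p = 0.1 each against control, the smallest that 3 against 3 allows, two-sided) and 23.8% ± 2.7 with acetochlor (p = 0.7).

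Transcripts of 1 Trinity gene, by the name without its isoform number and last digit, went in the same or opposite directions at rates within those of shuffles. If the last digit marks separate assemblies, such transcripts need not belong to 1 gene. Rates like the shuffled ones would then follow from the grouping, so they do not show how transcripts of 1 gene behaved. Of the 1131 Trinity genes with at least 2 transcripts called with S-metolachlor, 616 had calls in both directions, against a mean of 591 when directions were shuffled among the called transcripts (531 to 656 over 1000 shuffles), and 69 of 138 with trifluralin (mean 69.9), 51 of 109 with pendimethalin (53.6) and 26 of 65 with acetochlor (32.3).

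The last digit of the transcript names went with the group in which a transcript was highest. Of the names ending in 4, 32.7% had their highest mean CPM with pendimethalin, against 13.5% over all names, and of those ending in 2, 30.3% had it with acetochlor, against 14.7%. Of the names ending in 1, 48.3% had it with S-metolachlor, against 35.1%, with the set described next left out. Names ending in 3 and 5 lay at 0.64 to 1.15 and 0.68 to 1.12 times the overall shares over the 5 groups. If the digit marks the group whose reads were assembled, the listing of transcripts favours that group.

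A set of 1373 transcripts stood out in S-metolachlor replicate 1, by a rule settled after looser ones had been tried (at least 20 counts there, at least 4 times replicate 2, and a mean under 2 in the 12 libraries of the other groups). They held 148626 counts in replicate 1 (0.6305% of the library), 6318 in replicate 2 and 15250 in replicate 3, against at most 666 in any of the 12 others, and 98.6% of their names end in 1, against 24.4% of the rest. The tables argue against depth, since the totals of the set differed 9.7-fold between replicates 1 and 3 and the library totals had a ratio of 0.99. Reads from another organism or a mixed sample stay open, since the set ranked alike in replicates 1 and 3 (Spearman 0.63 across transcripts), although its ranks also went with the 12 other libraries (0.44). A response shared unevenly by the 3 libraries stays open too, since the lower of the totals in replicates 2 and 3 was 9.5 times the highest of the 12 others. A further 111 transcripts had 10211, 6821 and 6782 counts in replicates 1, 2 and 3, and 110 were called higher. These 111 were chosen for at least 20 counts in each of the 3 libraries, under 4 times apart, and a mean under 2 in the 12 others. Their evenness and calls therefore followed from the choice and speak for neither source. The source of the set was not identified, and 2 transcripts named in the report, TRINITY_DN8729_c0_g2_i1_1 and TRINITY_DN12301_c0_g1_i1_1, show its pattern although their mean in the 12 others is over 2.

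Pendimethalin replicate 3 departed from its group along the trifluralin against control difference, with a correlation across 7544 transcripts of -0.51. Replicates 1 and 2 were at 0.45 and 0.24 (deviations of 3 replicates sum to 0). On this axis, which uses their libraries, the controls lay at -0.08, 0.59 and -0.54, and trifluralin at -0.3, -0.27 and 0.56. S-metolachlor and acetochlor libraries lay between -0.17 and 0.22. The deviations of pendimethalin replicate 3 had the highest SD of the 15 libraries (0.77, the next 0.59). Of the 7 axes looked at, trifluralin against acetochlor gave the strongest correlation (-0.57) and was tested first; the axis against control was then taken in its place, and the test of a single wrong label added, with these values known. The tables argue against a trend on transcript length, inferred from counts and FPKM, since the deviations correlated at -0.02 with its log2. They argue against a swap with a control library too. Of the 3 controls, 0 correlated better with pendimethalin replicates 1 and 2 than with the other controls. However, the split that exchanges replicate 3 with control replicate 2 called the 679 transcripts given above. A single wrong label cannot be told apart from a weaker response, since both would bring replicate 3 nearer to another group. It correlated better with acetochlor (0.948) than with its own group (0.925). Replicates 1 and 2 had higher means with trifluralin (0.957 and 0.947) than with their own group (0.939 and 0.941). Those own-group means include replicate 3, however, and replicates 1 and 2 correlated at 0.954 with each other. A weaker response in replicate 3 was not settled by the -0.51 either, since control replicates 2 and 3 lay at 0.47 and -0.49 on the trifluralin against acetochlor axis, which uses no controls, so that untreated libraries varied along it as well.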
